A study of Mus musculus with 12 samples.

How the data were processed

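Messenger RNA was sequenced from cells sorted as PI-negative, CD45-positive, CD11B-positive and LY6G/SIGLECF-negative from mouse tibialis anterior muscle, 5 days after notexin injury, per the labels. The labels give Ifngr1 wt/null or null/null mice treated daily with isotype or anti-TNF neutralizing antibody, 3 samples in each of the 4 groups and 12 in all. They do not say whether each sample was a separate mouse. Sample titles start with 40 or 46, with 1 title starting with 46 in each group, and the meaning of that number is not given. A letter and a digit follow, also without a stated meaning, and no fit used them. Titles 40A2 and 40A3 were anti-TNF samples, and 40B1 and 40B2 were isotype samples. Titles 40C1 and 40C2 were anti-TNF samples, and 40C3 and 40C4 were isotype samples. Replicates were numbered in the order in which the samples were listed, so a number pairs nothing across groups.

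The deposited table holds counts per gene symbol, not normalized: the values are whole numbers with totals of 23.2 to 29.9 M counts per sample and 24421 symbols. Per the labels, RNA was extracted with an RNeasy Micro kit, libraries were made with a NEBNext Ultra II stranded mRNA kit, and paired-end reads came from a NextSeq instrument. The processing notes of the labels name bcl2fastq 2.20, STAR, Bowtie and the mouse genome build mm10 without saying what each was used for. The counting tool, strand setting, annotation and any earlier filter were not given in the sources used here. Of the symbols, 95.0% were found in the RefSeq gene table used for positions, which is on the same build under the name GRCm38.

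The 12 sample columns were matched to the samples by title, with 0 left unmatched. Genes were kept by filterByExpr on the 4 groups, which left 12981 genes holding at least 99.97% of the counts of each library. Counts were scaled by TMM in edgeR 4.0.16 (R 4.3.3) and fitted with robust quasi-likelihood models of the 4 group means on all 12 samples. The biological coefficient of variation was 0.179. The 8 comparisons were the antibody in each genotype, the genotype under each antibody, both perturbations against neither, the interaction, and the averages of the antibody and the genotype effects. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within its comparison. All tests were two-sided. Levels are given as CPM (counts per M counts, where M is mega) with TMM scaling, and log2 CPM values used a prior count of 2.

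Gene lists for pathways and for markers of macrophage states and of other cells that the gate could hold were fixed from general knowledge, 30 in all with 524 genes. Of these, 517 matched a symbol of the table, 5 of them under an older symbol, and Rigi, Ly6g, Trac, Trbc1, Trbc2, Igkc and Ighm did not. The 26 lists with at least 3 measured members were tested with camera in limma 3.58.1 at its preset correlation between genes of 0.01, with correction over the lists in each comparison. The sex-linked list served as a check and was not tested. Calls with all libraries, and the adjusted p of calls without the 2 libraries that stand apart, are given with camera at an estimated correlation, which for the IFN-γ-inducible list was 0.785. Calls with 1 library left out, and counts of calls that held, use the preset correlation alone. List members are also counted after correction over the list alone. List means were compared between genotypes and between antibodies by exact permutation within strata, a test added after the data were seen.

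Genes were named by a rule: the ligands and receptors Ifngr1, Ifngr2, Tnf, Tnfrsf1a and Tnfrsf1b, the 8 largest rises and 8 largest falls past the threshold in each comparison (5 each way for the interaction) with a mean log2 CPM of at least 2, up to 4 members per list past the threshold or up to 2 as values where none passed, and sex-linked and other cell markers as checks. Placeholder symbols were named only as list members. Genes named outside this rule are said to have been chosen after their values were seen. Groups, comparisons, tests, lists, the naming rule and the first set of other settings were chosen before the data were examined.

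Other settings chosen at that time were DESeq2 1.42.0, limma voom with sample quality weights, relative log expression scaling, no filter (a total count of at least 1), a stricter filter (1 CPM in at least 3 samples), the title number as a block, only samples titled 40, only the groups compared, genes without those within 20 Mb of Ifngr1, each library left out in turn, camera with an estimated correlation and fry. Added after the data were seen were fits without the 2 libraries that stand apart, the same with the title number as a block or with an estimated correlation for the lists, and list tests with relative log expression scaling, with the block and without each library. Effects of different comparisons were set side by side across all tested genes by Pearson and Spearman correlation, with 50 simulated draws of unchanged groups.

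Depth per library and group is given in the report. Counting error was small beside the spread between libraries: among the 66 pairs of libraries, within and between groups, the chi-square per degree of freedom was 10.6 to 138. The 10 most abundant genes held 11.5% to 13.8% of a library. The steps were tested on simulated data with the dispersions of these libraries. For genotype under isotype, 43.3%, 73.1% and 98.5% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, with 12 false calls. For the antibody in wt/null these were 32.8%, 67.2% and 93.9% with 4 false calls, for the averaged genotype effect 53.7%, 77.6% and 92.4% with 5, and for the averaged antibody effect 65.7%, 85.1% and 97.0% with 11. A list shifted 1.4-fold was called in 5 of 5 draws, and 1 of 112 tests of other lists was called. Genes were drawn independently of one another there, so this does not give the rate of false list calls in the real libraries. Other splits of the real libraries called a median of 10 lists for genotype on average and 12 for the interaction. No sample was left out of the comparisons as given.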

Results

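The transcriptomes were those of myeloid cells sorted from regenerating mouse tibialis anterior muscle on day 5 after injury with notexin, a snake toxin that destroys muscle fibres. Mice were Ifngr1 wt/null or null/null and received a TNF-neutralizing antibody or an isotype antibody daily. Ifngr1 encodes the ligand-binding chain of the receptor for interferon gamma (IFN-γ). The 4 groups held 3 libraries each, and the question was which genes of these cells depended on the receptor, on TNF, or on their combination. Sequencing depth was 25.4 ± 2.28 M counts (mean ± SD, n = 3) in wt/null isotype and 26.0 ± 0.294 M in wt/null anti-TNF. It was 26.8 ± 3.03 M in null/null isotype and 26.0 ± 0.477 M in null/null anti-TNF. Depth comparisons between groups gave exact permutation p between 0.552 and 1 (8 tests, where 0.1 was the smallest p a comparison of 3 with 3 could give). The p-values of single genes and of exact permutations below measure spread between samples, and the labels do not state that each sample was a separate mouse. Those of camera at its preset correlation set the genes of a list against the other genes. They measure spread between genes and do not show how well a list repeats between samples.

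Ifngr1 itself separated the genotypes in every library. It averaged 232 ± 6.92 CPM (counts per M counts of the library, mean ± SD, n = 3) in wt/null isotype and 242 ± 13.6 in wt/null anti-TNF. It averaged 88.7 ± 1.33 in null/null isotype and 96.4 ± 19.4 in null/null anti-TNF, which was 38.3% and 39.9% of the wt/null level under the same antibody. The highest null/null library had 119 CPM and the lowest wt/null library 226 CPM. An exact permutation within antibody gave p = 0.005, the smallest that 400 arrangements allow. Ifngr1 lies on chromosome 10 from 19591949 to 19610229. Of the 108 tested genes within 20 Mb of it, 0 were called for genotype averaged over antibody and 1.85% had an unadjusted p below 0.05, against 2.45% of the other genes. The structure of the null allele was not given in the sources used here, so the transcript that remained could come from exons the allele keeps.

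**Figure D1:**
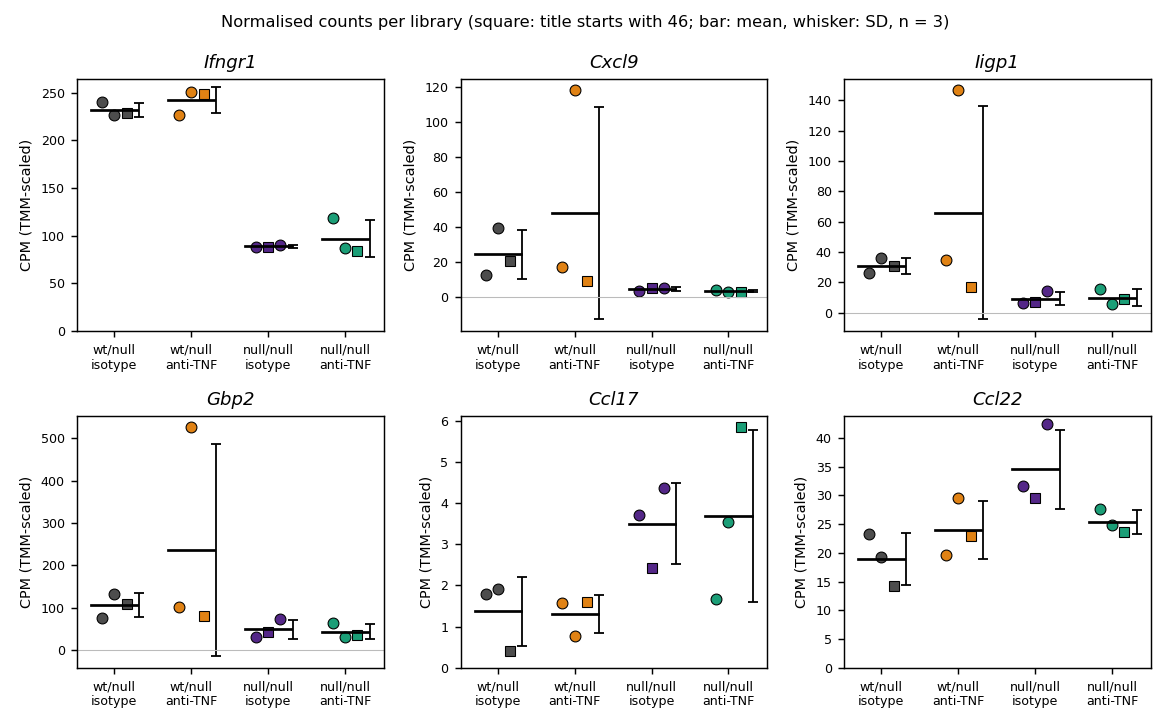
CPM (vertical axis) of Ifngr1 and of 5 other genes in each of the 12 libraries by group (horizontal axis), with the mean as a bar and the SD as a whisker, n = 3; squares are libraries whose title starts with 46. Ifngr1 was at most 119 CPM in null/null and at least 226 CPM in wt/null libraries, and Gbp2 reached 525 CPM in a wt/null anti-TNF library.

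Variation between the samples followed 2 libraries more than the groups. On the first principal component (34.4% of variance) wt/null anti-TNF replicate 2 scored 54.2 and null/null anti-TNF replicate 1 scored 45.9, while the others lay between -20.8 and -3.47. In these libraries the proteases Mmp9 and Ctsk, abundant in osteoclast-like cells, were at 6.80 and 19.2 CPM (Mmp9) and 21.0 and 35.9 CPM (Ctsk). The others held 171 to 1091 CPM of Mmp9 and 261 to 1233 CPM of Ctsk. Flt3, a receptor of dendritic cells, was at 87.3 and 89.3 CPM against 20.4 to 32.1. The cytotoxic granule gene Gzma was at 5.24 and 1.82 CPM against at most 0.477. Cd8a was at 5.65 and 2.99 CPM against 0.304 to 1.09. Ifng was at 2.91 and 1.48 CPM against at most 0.427. These genes were chosen after the values were seen, except the fixed cell markers Flt3, Gzma and Cd8a. Both libraries came from anti-TNF mice, 1 per genotype, so the leading antibody results below are also given without them. The neutrophil gene Ltf was at 7.24 CPM in null/null isotype replicate 1 and at most 0.589 in the others. Xist had 0 to 2 counts in every library while the Y-linked Ddx3y had 1009 to 2890 counts and Uty 379 to 1003, so every sample read as male.

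**Figure D2:**
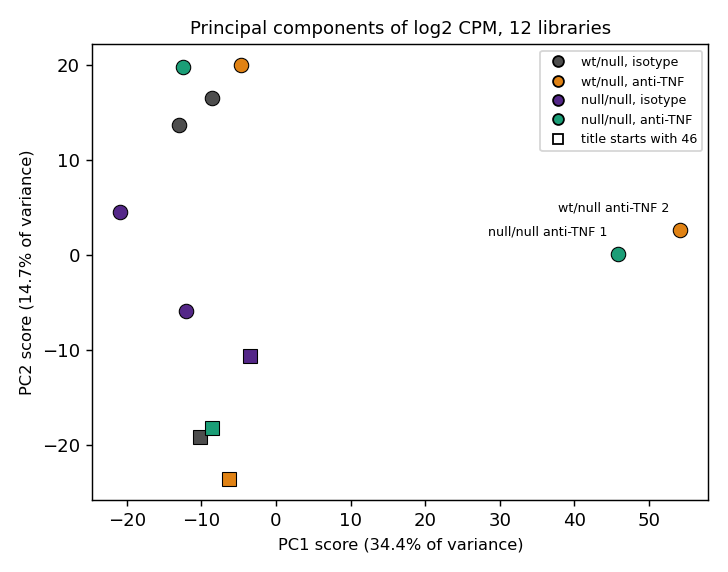
Scores of the 12 libraries on the first (horizontal) and second (vertical) principal components, coloured by group, with squares for titles that start with 46. The 2 named libraries lay at 54.2 and 45.9 on the first component and the other 10 between -20.8 and -3.47.

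Loss of the receptor, averaged over both antibodies, went with lower Ifngr1 and with lower estimates of the genes that IFN-γ induces. Cxcl9, a chemokine that draws activated T cells, averaged 24.5 ± 13.9 CPM (mean ± SD, n = 3) in wt/null isotype and 4.80 ± 1.13 in null/null isotype. Under anti-TNF it averaged 48.1 ± 60.9 in wt/null and 3.45 ± 0.720 in null/null. The GTPase Iigp1, which attacks vacuoles of intracellular microbes, averaged 31.0 ± 5.19, 66.0 ± 70.4, 9.29 ± 4.43 and 10.1 ± 5.33 CPM in wt/null isotype, wt/null anti-TNF, null/null isotype and null/null anti-TNF. In the same order Gbp2, another such GTPase, averaged 106 ± 28.2, 236 ± 251, 49.0 ± 22.1 and 44.1 ± 17.4. Over all 12981 genes edgeR called 1 gene, Ifngr1 (log2 fold change -1.36 ± 0.08, here and below estimate ± SE, 95% interval -1.54 to -1.17, adjusted p = 1.43e-05). At unadjusted p < 0.05 there were 319 genes, fewer than the 649 that would come by chance. DESeq2 called 4, adding Cxcl9, Serpina3f and Pvr, the last of which was higher and all of which were named after the values were seen. limma voom called 1. Every one of the 31 measured IFN-γ-inducible genes had a lower estimate in null/null (median log2 fold change -0.77), and camera called the list (adjusted p = 1.34e-38; adjusted p = 0.198 with an estimated correlation). The mean log2 CPM of the list was 4.77 ± 0.754 in wt/null and 3.84 ± 0.399 in null/null (mean ± SD, n = 6, exact permutation within antibody p = 0.01, 0.173 after correction over the lists). Adjusted over the list alone, 10 members were lower, against 0 over all genes. They included Cxcl9 (-3.07 ± 0.62, adjusted p = 0.0178), Iigp1 (-2.22 ± 0.51, adjusted p = 0.0233), Gm4951 (-1.51 ± 0.40, adjusted p = 0.0305) and Gbp2 (-1.77 ± 0.48, adjusted p = 0.0305). The camera call remained without the 2 libraries that stand apart (adjusted p = 3.21e-66; adjusted p = 0.0433 with an estimated correlation, in a fit chosen after the data were seen), and Cxcl9 was at -2.22, Iigp1 at -1.79 and Gbp2 at -1.27. Several of these genes belong to families of near-identical copies, among them the Gbp and Tgtp genes, so the share of each copy is uncertain.

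The genes that load peptides on MHC class I had lower estimates in 18 of 18 (median log2 fold change -0.28, camera adjusted p = 4.09e-14; adjusted p = 0.296 with an estimated correlation). The proteasome activator Psme2 was at -0.25 ± 0.10 and the class I transactivator Nlrc5 at -0.55 ± 0.22. Type I interferon-stimulated genes were lower in 33 of 34 (median -0.15, adjusted p = 2.28e-05; adjusted p = 0.715 with an estimated correlation), a call that ended without wt/null anti-TNF replicate 2 (0.194), null/null isotype replicate 1 (0.239) or null/null anti-TNF replicate 2 (0.341). So were MHC class II genes in 11 of 13 (adjusted p = 0.00226; adjusted p = 0.682 with an estimated correlation), a call that ended without wt/null anti-TNF replicate 2 (0.579) or null/null isotype replicate 1 (0.239). Cell cycle genes were lower in 27 of 31 (adjusted p = 2.28e-05; adjusted p = 0.682 with an estimated correlation). NF-κB target genes were higher in 29 of 36 (median 0.10, adjusted p = 0.000378; adjusted p = 0.682 with an estimated correlation). The cell cycle call ended without null/null anti-TNF 1 (0.291), and the NF-κB call without wt/null anti-TNF 1 (0.112) or 3 (0.0825), null/null isotype 2 (0.0743) or null/null anti-TNF 1 (0.0838). The IFN-γ-inducible, MHC class I and endothelial calls held whichever library was left out. Exact permutation of list means within antibody gave p = 0.1 for MHC class I (0.52 after correction over the lists), 0.435 for type I interferon-stimulated genes, 0.465 for MHC class II, 0.37 for cell cycle and 0.435 for NF-κB targets (0.826 each after correction).

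Chemokine genes as a list were higher in 16 of 23 (adjusted p = 0.00151; adjusted p = 0.233 with an estimated correlation). The members that rose past the threshold over the list alone were Ccl17 and Ccl22, the ligands of Ccr4 that attract regulatory and type 2 T cells. Ccl17 averaged 1.38 ± 0.834, 1.31 ± 0.462, 3.50 ± 0.980 and 3.68 ± 2.09 CPM (mean ± SD, n = 3) in wt/null isotype, wt/null anti-TNF, null/null isotype and null/null anti-TNF. In the same order Ccl22 averaged 18.9 ± 4.55, 24.0 ± 5.04, 34.5 ± 6.93 and 25.4 ± 2.04 CPM. Adjusted over the list alone Ccl17 (1.42 ± 0.39, adjusted p = 0.0395) and Ccl22 (0.47 ± 0.14, adjusted p = 0.0415) were higher and Cxcl9 (adjusted p = 0.0132) lower, against 0 over all genes. Reparative macrophage genes were higher in 22 of 29 (adjusted p = 0.00574; adjusted p = 0.308 with an estimated correlation). Lysosome and efferocytosis genes were higher in 22 of 27 (adjusted p = 0.00584; adjusted p = 0.423 with an estimated correlation), and matrix remodelling genes in 24 of 30 (adjusted p = 0.0111; adjusted p = 0.399 with an estimated correlation). The list of TNF and IFN-γ ligands, receptors and signalling genes was called lower with 7 of 14 members lower (adjusted p = 0.000183; adjusted p = 0.399 with an estimated correlation), and Ifngr1 was its 1 member past the threshold over the list alone. Neutrophil markers were higher in 5 of 6 (adjusted p = 0.0269; adjusted p = 0.233 with an estimated correlation) and endothelial markers lower in 9 of 10 (adjusted p = 0.00129; adjusted p = 0.198 with an estimated correlation). Ptprb, a phosphatase of endothelial cells, was at -0.48 ± 0.16. Exact permutation of list means gave p = 0.02 for neutrophil and for endothelial markers (0.173 after correction), 0.085 for reparative genes (0.52), and 0.25, 0.425, 0.26 and 0.32 for chemokines, lysosome, matrix and signalling genes (0.826 each). Leaving out 1 library ended the calls of chemokines (adjusted p = 0.128 without wt/null anti-TNF 3), signalling genes (0.077 without wt/null anti-TNF 2) and reparative genes (0.0825 without wt/null anti-TNF 3, 0.0734 without null/null isotype 3). Lysosome genes were not called without wt/null isotype 3 (0.171) or wt/null anti-TNF 2 (0.177). Matrix genes were not called without wt/null anti-TNF 2 (0.189), null/null isotype 2 (0.0516) or null/null anti-TNF 2 (0.341). Neutrophil markers were not called without wt/null anti-TNF 1 (0.0696) or 3 (0.0825), null/null isotype 1 (0.239) or null/null anti-TNF 1 (0.358).

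**Figure D3:**
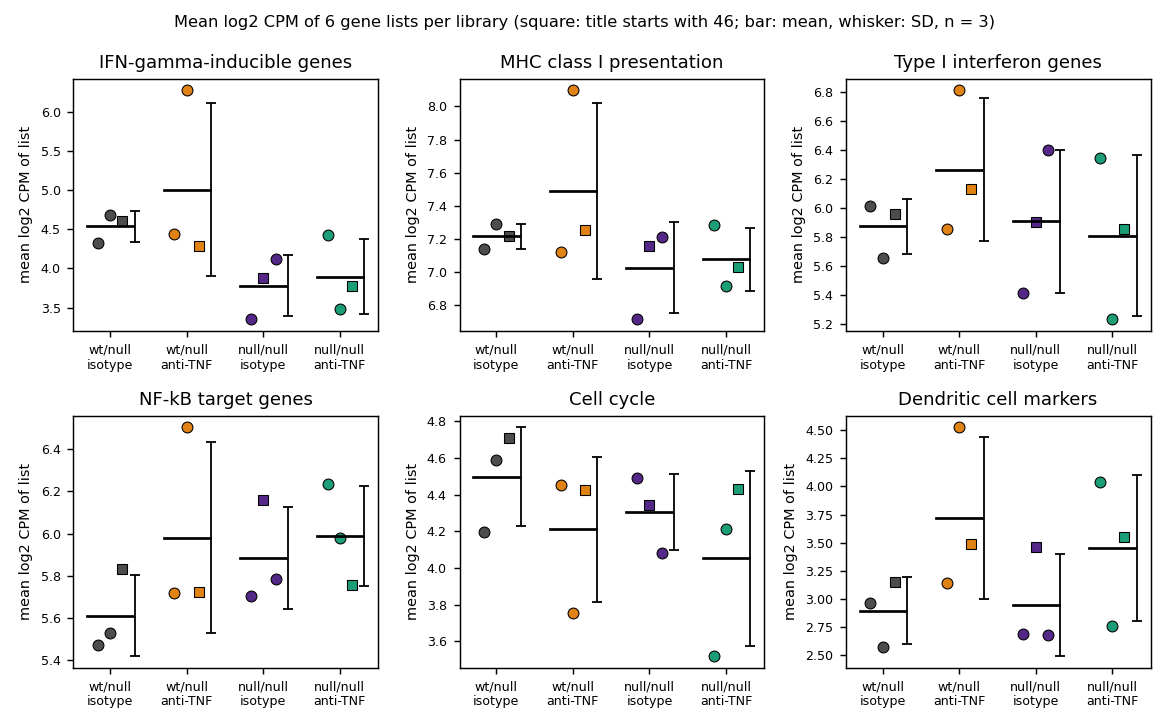
Mean log2 CPM of 6 gene lists (vertical axis) in each of the 12 libraries by group (horizontal axis), with the mean as a bar and the SD as a whisker, n = 3; squares are libraries whose title starts with 46. The IFN-γ-inducible list averaged 3.84 in null/null and 4.77 in wt/null libraries, and wt/null anti-TNF replicate 2 was the highest library in all but the cell cycle panel.

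Under isotype antibody the loss of the receptor went with lower estimates of most IFN-γ-inducible genes and higher estimates of most NF-κB targets and chemokines. Ifngr1 was the 1 gene edgeR called (-1.39 ± 0.12, adjusted p = 0.000643), with 234 genes at unadjusted p < 0.05 where 649 would come by chance. DESeq2 called 2 genes, Ifngr1 and Ptprb, and limma voom 1. IFN-γ-inducible genes were lower in 28 of 31 (median -0.46, camera adjusted p = 3.38e-11; adjusted p = 0.551 with an estimated correlation). Cxcl9 was at -2.34 ± 0.86 and Iigp1 at -1.73 ± 0.72, and 0 members passed over the list alone. NF-κB target genes were higher in 35 of 36 (median 0.21, adjusted p = 5.49e-08; adjusted p = 0.551 with an estimated correlation). Nfkb2, a subunit of NF-κB that NF-κB itself induces, averaged 152 ± 4.4 CPM (mean ± SD, n = 3) in wt/null and 182 ± 6.42 in null/null, a log2 fold change of 0.26 ± 0.07. Chemokines were higher in 21 of 23 (adjusted p = 0.000163; adjusted p = 0.316 with an estimated correlation). Ccl22 rose by 0.87 ± 0.20 (adjusted p = 0.0208 over the list alone, against 0 calls over all genes beyond Ifngr1). Pro-inflammatory macrophage genes, among them Cd80 (0.35 ± 0.14), were higher in 17 of 20 (adjusted p = 0.00114; adjusted p = 0.551 with an estimated correlation). Reparative macrophage genes were also higher, in 21 of 29 (adjusted p = 0.0206; adjusted p = 0.551 with an estimated correlation). Lysosome genes were higher in 19 of 27 (adjusted p = 0.0206; adjusted p = 0.624 with an estimated correlation) and glycolysis genes in 13 of 17 (adjusted p = 0.0224; adjusted p = 0.739 with an estimated correlation). Cell cycle genes were lower in 25 of 31 (adjusted p = 0.00252; adjusted p = 0.792 with an estimated correlation) and MHC class I genes in 17 of 18 (adjusted p = 0.0112; adjusted p = 0.792 with an estimated correlation). Endothelial markers were lower in 8 of 10 (adjusted p = 0.0112; adjusted p = 0.316 with an estimated correlation). Ptprb fell from 4.31 ± 0.751 to 1.96 ± 0.178 CPM (log2 fold change -1.14 ± 0.22, adjusted p = 0.00247 over the list alone). The IFN-γ-inducible, NF-κB and chemokine calls held whichever library was left out. MHC class I genes lost theirs without wt/null isotype 2 (adjusted p = 0.13) or null/null isotype 1 (0.909), pro-inflammatory genes without wt/null isotype 2 (0.12) and reparative genes without null/null isotype 3 (0.353). Without wt/null isotype 2, wt/null isotype 3 or null/null isotype 3 neither lysosome genes (0.0514, 0.63 and 0.109) nor cell cycle genes (0.12, 0.361 and 0.311) were called. Glycolysis genes were not called without wt/null isotype 1 (0.197) or 2 (0.101) or null/null isotype 3 (0.57), nor endothelial markers without wt/null isotype 1 (0.205) or null/null isotype 1 (0.206).

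With TNF neutralized the loss of the receptor went with lower estimates of the IFN-γ-inducible genes, at a median log2 fold change of -1.09. The estimates of 30 of 31 members were lower (camera adjusted p = 8.55e-33, and 0.531 with an estimated correlation). Adjusted over the list alone 11 members were lower, against 0 over all genes. Cxcl9 changed by -3.80 ± 0.90, Iigp1 by -2.71 ± 0.74, Gbp2 by -2.42 ± 0.69 and Gm4951 by -1.86 ± 0.57 (each adjusted p = 0.0384 over the list alone). Part of this size came with wt/null anti-TNF replicate 2, which held 118 CPM of Cxcl9, 147 of Iigp1 and 525 of Gbp2. Without the 2 libraries that stand apart Cxcl9 was at -2.11, Iigp1 at -1.84 and Gbp2 at -1.42, and the list remained called (adjusted p = 3.4e-42; adjusted p = 0.149 with an estimated correlation). edgeR and limma voom called 1 gene, Ifngr1 (-1.33 ± 0.12 in edgeR, adjusted p = 0.00103), with 257 genes at unadjusted p < 0.05 where 649 would come by chance. DESeq2 called 2, Cxcl9 and Ifngr1. MHC class I genes were lower in 18 of 18 (median -0.47, adjusted p = 6.47e-17; adjusted p = 0.531 with an estimated correlation), with Psme2 at -0.47 ± 0.14 and Nlrc5 at -0.80 ± 0.32. Type I interferon-stimulated genes were lower in 34 of 34 (adjusted p = 1.36e-14; adjusted p = 0.572 with an estimated correlation), among them the nucleic acid sensor Zbp1 (-1.06 ± 0.43). Of the MHC class II genes 12 of 13 were lower (adjusted p = 4.77e-05; adjusted p = 0.581 with an estimated correlation), a call that ended without wt/null anti-TNF replicate 2 (0.804). Oxidative phosphorylation genes were lower in 27 of 27 by a median of -0.09 (adjusted p = 9.01e-05; adjusted p = 0.635 with an estimated correlation). TNF and IFN-γ signalling genes were lower in 9 of 14 (adjusted p = 0.00035; adjusted p = 0.572 with an estimated correlation) and cell cycle genes in 28 of 31 (adjusted p = 0.00313; adjusted p = 0.724 with an estimated correlation). Cell death genes were lower in 17 of 24 (adjusted p = 0.0328; adjusted p = 0.724 with an estimated correlation) and dissociation stress and immediate early genes in 18 of 18 (adjusted p = 0.0387; adjusted p = 0.727 with an estimated correlation). Chemokines as a list were not called, though Cxcl9 passed over that list alone (adjusted p = 0.0414). The calls of IFN-γ-inducible, MHC class I and type I interferon-stimulated genes held whichever library was left out. Signalling genes lost theirs without wt/null anti-TNF 2 (adjusted p = 0.544) or null/null anti-TNF 3 (0.0964), and oxidative phosphorylation genes without wt/null anti-TNF 3 (0.995) or null/null anti-TNF 1 (0.113). Cell cycle genes lost it without wt/null anti-TNF 1 (0.579) or 3 (0.475) or null/null anti-TNF 1 (0.113, turned higher). Cell death genes lost it without wt/null anti-TNF 2 (0.367, turned higher), null/null anti-TNF 2 (0.621) or null/null anti-TNF 3 (0.225). Dissociation stress and immediate early genes were called higher without wt/null anti-TNF 2 (0.0225) and not called without null/null anti-TNF 3 (0.994).

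TNF neutralization in wt/null mice moved no gene past the threshold. Tnf itself averaged 23.7 ± 3.56 CPM (mean ± SD, n = 3) under isotype and 53.5 ± 44.8 under anti-TNF (log2 fold change 1.17 ± 0.48), with 105 CPM in wt/null anti-TNF replicate 2. Cd209a, a lectin of monocyte-derived dendritic cells, averaged 37.9 ± 5.55 and 79.0 ± 38.7 CPM. edgeR called 0 genes, with 581 at unadjusted p < 0.05 where 649 would come by chance, and DESeq2 and limma voom also called 0. Camera called 14 lists, each with adjusted p = 0.442 with an estimated correlation, and 11 of the 14 ended without wt/null anti-TNF replicate 2. The dissociation stress and immediate early list, a sign of sample handling as well as of activation, averaged 9.26 log2 CPM in that library and at most 8.76 in the others. Without both libraries that stand apart 5 lists were called, 4 of them among the 14 and in the same direction. NF-κB targets were higher in 30 of 36 (median 0.41, adjusted p = 2.65e-08), with the neutrophil chemokine Cxcl1 at 1.31 ± 0.47 and Il6 at 0.86 ± 0.36. This list was not called without the 2 libraries that stand apart (adjusted p = 0.0736), and Cxcl1 was at 0.71. IFN-γ-inducible genes were higher in 30 of 31 (median 0.74, adjusted p = 4.45e-07), with Cxcl10 at 0.86 ± 0.38 and Irf1 at 0.74 ± 0.35. Without the same libraries this list turned lower and was not called (adjusted p = 0.0769). Dissociation stress and immediate early genes were higher in 18 of 18 (adjusted p = 2.65e-08), type I interferon-stimulated genes in 34 of 34 (adjusted p = 4.11e-08) and MHC class I genes in 17 of 18 (adjusted p = 6.2e-06). All 13 MHC class II genes were higher (adjusted p = 4.11e-08), with H2-Oa at 1.35 ± 0.49 and H2-Ob at 0.88 ± 0.35. Dendritic cell markers were higher in 12 of 13 (adjusted p = 9.41e-07), a call that held without the 2 libraries at the preset correlation (adjusted p = 0.000555) but not with an estimated correlation (adjusted p = 0.909). Markers of NK cells were higher in 7 of 7 (adjusted p = 0.00132), of T cells in 5 of 6 (adjusted p = 0.0301) and of myogenic cells in 8 of 10 (adjusted p = 0.00164). Pro-inflammatory genes were higher in 14 of 20 (adjusted p = 0.00172), cell death genes in 21 of 24 (adjusted p = 0.00421) and chemokines in 16 of 23 (adjusted p = 0.00458). Cell cycle genes were lower in 29 of 31 (median -0.31, adjusted p = 3.39e-06), with the replication helicase subunit Mcm2 at -0.35 ± 0.16, and were not called without the 2 libraries (adjusted p = 0.123). In each of the 14 lists 0 members passed over the list alone. The calls of MHC class II genes, dissociation stress and immediate early genes and dendritic cell markers held whichever library was left out. Without wt/null anti-TNF 2 the adjusted p was 0.142 for IFN-γ-inducible genes and 0.931 for MHC class I genes (both turned lower), 0.142 for type I interferon-stimulated genes and 0.0716 for NF-κB targets. It was 0.41 for pro-inflammatory genes, 0.167 for chemokines, 0.261 for cell cycle genes, 0.97 for cell death genes, and 0.0633, 0.465 and 0.556 for markers of myogenic, NK and T cells. Pro-inflammatory genes were also not called without wt/null isotype 2 (0.123), nor chemokines without wt/null isotype 1 (0.0593).

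In null/null mice the antibody moved 0 genes in edgeR, DESeq2 and limma voom, with 452 at unadjusted p < 0.05 in edgeR where 649 would come by chance. Mcm2 averaged 35.6 ± 4.31 CPM (mean ± SD, n = 3) under isotype and 25.3 ± 4.74 under anti-TNF (-0.49 ± 0.16), and Mcm3, of the same helicase, was at -0.37 ± 0.15. Cell cycle genes were lower in 30 of 31 (median -0.19, adjusted p = 3.74e-05; adjusted p = 0.823 with an estimated correlation). That call ended without null/null isotype 1 (0.0722) or null/null anti-TNF 1 (0.668), and without the 2 libraries that stand apart it had adjusted p = 0.804. Glycolysis genes were lower in 14 of 17 (adjusted p = 0.00127; adjusted p = 0.823 with an estimated correlation), with Pgam1 at -0.30 and Pkm at -0.25. Oxidative phosphorylation genes were lower in 23 of 27 (adjusted p = 0.00127) and lysosome genes in 19 of 27 (adjusted p = 0.0167), both with adjusted p = 0.823 with an estimated correlation. Markers of myogenic cells were higher in 10 of 10 (adjusted p = 0.00242; adjusted p = 0.823 with an estimated correlation), led by the satellite cell factor Pax7 (1.57 ± 0.60). Dendritic cell markers were higher in 11 of 13 (adjusted p = 0.00671), markers of mast cells and basophils in 5 of 5 (adjusted p = 0.0167) and of NK cells in 6 of 7 (adjusted p = 0.0301), each with adjusted p = 0.823 with an estimated correlation. MHC class II genes were higher in 12 of 13 (adjusted p = 0.0216; adjusted p = 0.875 with an estimated correlation). Ccr2, the receptor that brings monocytes into injured tissue, was at 0.71 ± 0.26, though its list of Ly6C-high monocyte genes was not called. Without the 2 libraries that stand apart that list was called lower (adjusted p = 0.0139, and 0.687 with an estimated correlation). Ptprb was higher (0.95 ± 0.22, adjusted p = 0.0105 over the list alone, against 0 over all genes), though its list was not called. The 4 sex-linked genes measured were each higher over their list alone, with Uty at 0.73 ± 0.24 (adjusted p = 0.0367). Of these 9 list calls 4 held without the 2 libraries that stand apart, and none held whichever library was left out. Without null/null isotype 1 the adjusted p was 0.905 for MHC class II genes, 0.206 for dendritic cell markers and 0.155 each for markers of myogenic, NK and mast cells. Without null/null anti-TNF 1 it was 0.523 for MHC class II genes, 0.993 for NK cell markers, 0.34 for dendritic cell markers and 0.0865 for oxidative phosphorylation genes. Without null/null isotype 3 it was 0.0503 for lysosome and for glycolysis genes, 0.0723 for oxidative phosphorylation genes and 0.273 for mast cell markers. Mast cell markers were also not called without null/null anti-TNF 2 (0.0696) or 3 (0.145), and without the latter neither lysosome genes (0.0644) nor dendritic cell markers (0.054) were.

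Averaged over genotype, the antibody gave the largest number of genes at unadjusted p < 0.05 among the 8 comparisons (949, where 649 would come by chance), and edgeR and limma voom called 0. DESeq2 called 6, named after the values were seen: Cd209a was higher and Adam8, Dnmt1, Glg1, Myh9 and Plxna1 lower. Mcm2 averaged 35.0 ± 2.94 and 27.5 ± 4.60 CPM (mean ± SD, n = 3) in wt/null isotype and wt/null anti-TNF, and Cd209a averaged 43.9 ± 10.7 and 71.2 ± 24.3 CPM in null/null isotype and null/null anti-TNF. Cell cycle genes were lower in 30 of 31 (median -0.24, camera adjusted p = 6.07e-08; adjusted p = 0.477 with an estimated correlation), with Mcm2 at -0.42 ± 0.11. Without the 2 libraries that stand apart the call ended (adjusted p = 0.244) and Mcm2 was at -0.28. Dendritic cell markers were higher in 12 of 13 (median 0.85, adjusted p = 1.87e-06; adjusted p = 0.477 with an estimated correlation), with Cd209a at 0.88 ± 0.24. This call held without the 2 libraries (adjusted p = 0.000706; adjusted p = 0.735 with an estimated correlation), where Cd209a was at 0.49. MHC class II genes were higher in 12 of 13 (adjusted p = 1.7e-06; adjusted p = 0.477 with an estimated correlation) and stayed called without the 2 libraries (adjusted p = 0.00545, and 0.735 with an estimated correlation). Markers of myogenic cells were higher in 10 of 10 (adjusted p = 7.65e-05; adjusted p = 0.477 with an estimated correlation), with the adhesion gene Cdh15 at 0.87 ± 0.26, and stayed called without the 2 libraries (adjusted p = 0.00101, and 0.735 with an estimated correlation). IFN-γ-inducible genes were higher in 30 of 31 (adjusted p = 0.000255; adjusted p = 0.592 with an estimated correlation), and without the 2 libraries they were called lower (adjusted p = 0.000706), a call lost with an estimated correlation (adjusted p = 0.735). Type I interferon-stimulated genes, higher in 31 of 34 (adjusted p = 0.0177; adjusted p = 0.675 with an estimated correlation), also turned lower without them (adjusted p = 0.00101; adjusted p = 0.902 with an estimated correlation). NF-κB targets were higher in 29 of 36 (adjusted p = 7.45e-05; adjusted p = 0.573 with an estimated correlation) but not without the 2 libraries (adjusted p = 0.815). Dissociation stress and immediate early genes were higher in 18 of 18 (adjusted p = 2.23e-06) and NK cell markers in 7 of 7 (adjusted p = 0.00059), both with adjusted p = 0.477 with an estimated correlation. Cell death genes were higher in 20 of 24 (adjusted p = 0.0108; adjusted p = 0.573 with an estimated correlation) and MHC class I genes in 17 of 18 (adjusted p = 0.00541; adjusted p = 0.592 with an estimated correlation). Endothelial markers were higher in 8 of 10 (adjusted p = 0.0392), glycolysis genes lower in 13 of 17 (adjusted p = 0.00581), lysosome genes lower in 23 of 27 (adjusted p = 0.00804) and matrix genes, with Mmp14 at -0.29 ± 0.08, lower in 18 of 30 (adjusted p = 0.0355). Each of these 4 had adjusted p = 0.477 with an estimated correlation. Markers of fibro-adipogenic progenitors were lower in 8 of 11 (adjusted p = 0.0447; adjusted p = 0.592 with an estimated correlation). Exact permutation of list means within genotype gave p = 0.03 for myogenic, 0.04 for endothelial and 0.045 for dendritic cell markers (0.39 each after correction), 0.08 for MHC class II and 0.21 for cell cycle genes, and at least 0.1 for the rest. Without the 2 libraries the same test gave 0.1, 0.15 and 0.19 for these markers in that order and 0.34 for MHC class II (0.99 each after correction). Without the 2 libraries 6 of the 16 calls held, 2 turned and 10 lists were called in all. No member of any of the 16 lists passed over the list alone, Cdh15 being the nearest (adjusted p = 0.051). The calls of MHC class II genes, NF-κB targets, cell cycle genes, dissociation stress and immediate early genes and markers of myogenic, NK and dendritic cells held whichever 1 library was left out. Without wt/null anti-TNF 2 the adjusted p was 0.987 for IFN-γ-inducible genes (turned lower), for MHC class I genes and for type I interferon-stimulated genes. It was 0.0547 for lysosome genes and endothelial markers, 0.112 for matrix genes, 0.409 for cell death genes and 0.296 for fibro-adipogenic markers. MHC class I genes were also not called without null/null isotype 1 (0.16) or null/null anti-TNF 1 (0.0504), lysosome genes without wt/null isotype 1 (0.0756), and cell death genes without null/null anti-TNF 1 (0.083). Matrix genes were not called without wt/null isotype 3 (0.134), null/null isotype 2 (0.102) or null/null anti-TNF 1 (0.229), nor glycolysis genes without wt/null anti-TNF 1 (0.0862). Type I interferon-stimulated genes (0.0517 to 0.987), fibro-adipogenic markers (0.0672 to 0.49) and endothelial markers (0.0504 to 0.117) lost their calls in 6, 7 and 8 of the 12 omissions.

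Cells exposed to both perturbations (null/null anti-TNF) were set against cells exposed to neither (wt/null isotype). The latter still carry 1 null allele of Ifngr1, and no group without a null allele was among the samples. Camera called cell cycle and IFN-γ-inducible genes lower, calls that were lost with an estimated correlation (adjusted p = 0.539 and 0.605) and with fry. edgeR and limma voom called 1 gene, Ifngr1 (-1.27 ± 0.12 in edgeR, adjusted p = 0.00173), with 276 genes at unadjusted p < 0.05 where 649 would come by chance. DESeq2 also called 1. Cell cycle genes were lower in 30 of 31 (median -0.41, camera adjusted p = 6.69e-17; adjusted p = 0.539 with an estimated correlation), with Mcm2 at -0.47 ± 0.16, and remained so without the 2 libraries that stand apart (adjusted p = 5.17e-07; adjusted p = 0.525 with an estimated correlation). IFN-γ-inducible genes were lower in 27 of 31 (adjusted p = 4.29e-08; adjusted p = 0.605 with an estimated correlation), with Cxcl9 at -2.82 ± 0.88 and Iigp1 at -1.62 ± 0.72. NF-κB targets were higher in 31 of 36 (adjusted p = 2.21e-10; adjusted p = 0.539 with an estimated correlation), with Cxcl1 at 1.25 ± 0.47. Chemokines were higher in 20 of 23 (adjusted p = 0.000183; adjusted p = 0.378 with an estimated correlation). Dissociation stress and immediate early genes were higher in 18 of 18 (adjusted p = 3.35e-05) and pro-inflammatory genes in 15 of 20 (adjusted p = 0.00827), both with adjusted p = 0.605 with an estimated correlation. Dendritic cell markers were higher in 12 of 13 (adjusted p = 0.000243; adjusted p = 0.561 with an estimated correlation), with Cd209a at 0.91 ± 0.34, and NK cell markers in 7 of 7 (adjusted p = 0.0172; adjusted p = 0.613 with an estimated correlation). Myogenic markers were higher in 10 of 10 (adjusted p = 0.00827), reparative macrophage genes in 20 of 29 (adjusted p = 0.0252) and neutrophil markers in 5 of 6 (adjusted p = 0.0342), each with adjusted p = 0.539 with an estimated correlation. MHC class II genes were higher in 12 of 13 (adjusted p = 0.0252), MHC class I genes lower in 17 of 18 (adjusted p = 0.0189) and fibro-adipogenic markers lower in 10 of 11 (adjusted p = 0.0252), each with adjusted p = 0.68 with an estimated correlation. Oxidative phosphorylation genes were lower in 21 of 27 (adjusted p = 0.0445; adjusted p = 0.75 with an estimated correlation). Of the 15 calls 7 held without the 2 libraries that stand apart, and those of IFN-γ-inducible genes, NF-κB targets, chemokines, cell cycle genes and dissociation stress and immediate early genes held whichever library was left out. Without null/null anti-TNF 1 none of the other 10 but MHC class I genes was called: the adjusted p was 0.885 for MHC class II genes, 0.668 for pro-inflammatory genes (turned lower), 0.0922 for reparative genes and 0.9 for oxidative phosphorylation genes. It was 0.872 for fibro-adipogenic markers (turned higher), 0.0922 for myogenic and dendritic cell markers, 0.517 for neutrophil markers and 0.93 for NK cell markers (turned lower). MHC class I genes were not called without wt/null isotype 2 (0.129), null/null anti-TNF 2 (0.404) or null/null anti-TNF 3 (0.145), and reparative genes not without wt/null isotype 3 (0.089) or null/null anti-TNF 2 (0.285). The MHC class II list also needed wt/null isotype 3 (0.151 without it), myogenic markers wt/null isotype 1 (0.0738) and NK cell markers wt/null isotype 2 (0.129). Fibro-adipogenic markers needed wt/null isotype 1 (0.088) and 2 (0.078) and null/null anti-TNF 3 (0.321). Pro-inflammatory, oxidative phosphorylation and neutrophil lists lost their calls in 6, 6 and 8 of the 12 omissions, with adjusted p of at least 0.0556, 0.0503 and 0.0682.

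The interaction asked whether the antibody acted differently in the absence of the receptor. edgeR, DESeq2 and limma voom called 0 genes, with 196 at unadjusted p < 0.05 in edgeR where 649 would come by chance. Camera called 10 lists, each with adjusted p = 0.838 with an estimated correlation. Type I interferon-stimulated genes had a lower antibody effect in null/null in 34 of 34 (median log2 difference -0.54, adjusted p = 2.47e-09), with Isg15 at -1.10 ± 0.61 and Isg20 at -0.97 ± 0.55. IFN-γ-inducible genes did so in 30 of 31 (adjusted p = 0.000404), with Cxcl10 at -1.07 ± 0.53, and MHC class I genes in 16 of 18 (adjusted p = 0.000404). Of the 10 calls 4 held without the 2 libraries that stand apart and 1 held without wt/null anti-TNF replicate 2 alone. NF-κB targets were lower in 34 of 36 and oxidative phosphorylation genes in 26 of 27 (both adjusted p = 4.08e-05). Pro-inflammatory genes were lower in 16 of 20 (adjusted p = 0.00226), dissociation stress and immediate early genes in 17 of 18 (adjusted p = 0.00291), MHC class II genes in 13 of 13 (adjusted p = 0.0137) and chemokines in 17 of 23 (adjusted p = 0.0155), with Ccl22 at -0.79 ± 0.28. Markers of mast cells and basophils were higher in 5 of 5 (adjusted p = 0.0125). Ptprb averaged 4.31 ± 0.751, 3.36 ± 0.655, 1.96 ± 0.178 and 3.79 ± 0.629 CPM (mean ± SD, n = 3) in wt/null isotype, wt/null anti-TNF, null/null isotype and null/null anti-TNF. Its interaction was 1.31 ± 0.31 (adjusted p = 0.0115 over the list alone, against 0 over all genes). Without wt/null anti-TNF 2 the adjusted p was 0.0503 for type I interferon-stimulated genes, 0.83 for NF-κB targets, 0.353 for pro-inflammatory genes, 0.419 for chemokines and 0.353 for mast cell markers. With the sign turned it was 0.0706 for IFN-γ-inducible genes, 0.794 for MHC class I genes, and 0.837 for MHC class II and for dissociation stress and immediate early genes. The call that remained, oxidative phosphorylation, ended without wt/null anti-TNF 3 (0.151). IFN-γ-inducible and MHC class I genes also needed null/null anti-TNF 2 (0.136 and 0.0527 without it), and chemokines wt/null isotype 1 (0.0847), null/null isotype 1 (0.0737) and null/null anti-TNF 3 (0.207). MHC class II genes, dissociation stress and immediate early genes and mast cell markers lost their calls in 5, 5 and 6 of the 12 omissions, with adjusted p of at least 0.0586, 0.0847 and 0.0527.

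Of the receptors, Ifngr1 alone passed the threshold in any comparison. Ifngr2, the signalling chain of the IFN-γ receptor, averaged 201 ± 14.2, 204 ± 6.74, 208 ± 9.06 and 208 ± 8.20 CPM (mean ± SD, n = 3) in wt/null isotype, wt/null anti-TNF, null/null isotype and null/null anti-TNF. In the same order the TNF receptor Tnfrsf1a averaged 199 ± 6.47, 204 ± 15.3, 215 ± 19.3 and 203 ± 6.65, and Tnfrsf1b averaged 681 ± 5.09, 679 ± 79.2, 723 ± 88.8 and 694 ± 25.0. For genotype averaged over antibody their log2 fold changes were 0.04 ± 0.06, 0.05 ± 0.06 and 0.06 ± 0.08. Tnf averaged 29.6 ± 5.21 CPM in null/null isotype and 36.0 ± 9.50 in null/null anti-TNF. Its log2 fold change was -0.13 ± 0.34 for genotype and 0.73 ± 0.34 for antibody (adjusted p = 0.66), and without the 2 libraries that stand apart the genotype value was 0.28. As lists, the 16 measured Ly6C-high monocyte genes (camera adjusted p from 0.0859 to 0.738) and the 14 muscle fibre markers (0.0881 to 0.904) were called in 0 of the 8 comparisons. Without the 2 libraries that stand apart the monocyte list was called lower for antibody in null/null (adjusted p = 0.0139), for genotype under anti-TNF (0.00576) and for the interaction (0.00814), and the muscle fibre list higher for genotype under anti-TNF (0.0253). With an estimated correlation none of these 4 was called (adjusted p = 0.687, 0.474, 0.82 and 0.64 in that order). Eosinophil (Siglecf, Ccr3), B and plasma cell (Jchain, Cd79b) and erythroid (Alas2) lists had too few measured genes for a list test. Jchain was at 16.9 CPM in wt/null anti-TNF replicate 2 and averaged 0.342 in null/null anti-TNF, a log2 fold change of -4.25 ± 1.30 for genotype under anti-TNF (adjusted p = 0.0162 over its list alone).

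Across the 12981 genes the antibody effects in the 2 genotypes had a Pearson r of 0.41 and a Spearman rho of 0.35, where simulated data gave r = -0.000642. Genes are not independent replicates, and without the 2 libraries that stand apart r was 0.0883. The genotype effects under the 2 antibodies had r = 0.17 and rho = 0.07, and r = 0.11 without these libraries. The antibody effect in wt/null and the genotype effect under isotype share wt/null isotype as control, which by itself makes r positive. They had r = 0.285 and rho = 0.251 where 50 simulated draws gave r = 0.50. Their covariance was 0.0204 against 0.0433, a difference from the simulation of -0.0229. The draws gave every group the same spread. In limma voom the wt/null isotype libraries had quality weights of 1.53, 1.73 and 1.01, against 0.499 and 0.481 in the 2 that stand apart. A simulated covariance that is too large could therefore give this difference, and it does not show opposed effects. For this pair r was 0.403 without the 2 libraries that stand apart and 0.166 at a mean log2 CPM of at least 4, settings that were not simulated. Cxcl9 and Iigp1 were among the genes whose genotype effects had the same sign under both antibodies.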

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

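The interaction test over gene lists and the counts over other splits of the samples were chosen before any result was seen, whereas the tests of the explanations in the next 2 paragraphs were chosen after. The antibody effect differed between the genotypes for 10 gene lists in the interaction test of camera. The adjusted p were 2.47e-09 for type I interferon-stimulated genes, 4.08e-05 for NF-κB targets, 4.08e-05 for oxidative phosphorylation, 0.000404 for IFN-γ-inducible genes and 0.000404 for MHC class I. They were 0.00226 for pro-inflammatory macrophage genes, 0.00291 for dissociation stress and immediate early genes, 0.0125 for mast cell and basophil markers, 0.0137 for MHC class II and 0.0155 for chemokines. Each had adjusted p = 0.838 with an estimated correlation. Groups of 3 are too small for a test of a single distant sample within its group.

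A source in 1 library, wt/null anti-TNF replicate 2, cannot be told apart from a difference between the genotypes. Removing it changed the mean difference of the lists by less than the SE with all libraries. That could not come out otherwise, because a distant library in so small a group also widens this SE. The size of the change therefore decides nothing. Removing null/null anti-TNF replicate 1 as well moved the difference back. Without wt/null anti-TNF replicate 2 alone, 1 of the 10 lists, oxidative phosphorylation, was still called in the same direction. The IFN-γ-inducible list went from -0.35 ± 0.74 (mean log2 difference ± SE between libraries) to 0.28 ± 0.43. The type I list went from -0.49 ± 0.53 to -0.21 ± 0.51 (adjusted p = 0.0503). Without null/null anti-TNF replicate 1 as well, 4 of the 10 held at the preset correlation: type I interferon-stimulated (-0.48 ± 0.47, adjusted p = 6.37e-13), pro-inflammatory (-0.43 ± 0.31, 0.000114), oxidative phosphorylation (-0.15 ± 0.14, 1.81e-05) and NF-κB genes (-0.12 ± 0.24, 0.0264). With an estimated correlation each of the 4 had adjusted p = 0.82 there. The IFN-γ-inducible list (0.02 ± 0.35, camera adjusted p = 0.334) and the MHC class I list (-0.03 ± 0.22, 0.194) did not return without both libraries. Why either library differs, in biology or in handling, was not tested.

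The library just named and null/null anti-TNF replicate 1 stand apart from the other 10. RNA from NK, T and dendritic cells is a candidate explanation for the genes that are higher there: of 26 measured markers of these cells, 19 (73.1%) were above all other 10 libraries in both, against 11.6% of the other 12955 genes, although some of these markers had been seen high before the test and markers of a cell type are not independent. The CD11B-positive gate would remove most T cells but not CD11B-positive NK or dendritic cells, and dendritic markers such as Cd209a and Ccr7 can also come from the myeloid cells studied, so the source stays open. Dilution by other cells as the cause of the genes that are lower there stays open. The 10 most abundant reparative macrophage genes were at a mean log2 difference of -0.045 (SD 0.16, 0 of 10 below all other libraries in both). The median of the 1625 lower genes was -0.48. These genes were selected for their fall in the same 2 libraries, so genes not selected in this way would lie above that median under most causes. This is the 3rd comparison made for it and was picked with its values known. With the lysosome list (-0.43) and 7 further osteoclast-type genes (-0.48) dilution could not be told from a loss of particular genes. Depth is argued against by 0 of the 2 libraries lying outside the range of the others, whereas an antibody effect on every animal stays open. The score of the genes that set the 2 libraries apart by 1.4 differed by 0.08 between the other 4 anti-TNF and the isotype libraries (exact permutation p = 0.21). These genes were selected to lie beyond all other 10 libraries, the other 4 anti-TNF ones included. That choice favours a small difference, so its size does not speak against such an effect.

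Other splits of the same libraries were fitted for each count. For comparisons of 3 with 3 the 10 splits are too few for a share under 0.05. The real gene counts and the highest of the other splits were 0 and 8 for the antibody in wt/null (10 of 10 splits as large), 1 and 0 for genotype under isotype (1 of 10), and 0 and 0 for the antibody in null/null (10 of 10). They were 1 and 0 for genotype under anti-TNF (1 of 10) and 1 and 0 for both perturbations (1 of 10). The list counts were 14 and 19 (7 of 10), 10 and 12 (4 of 10), 9 and 17 (7 of 10), 9 and 19 (7 of 10), and 15 and 13 (1 of 10) in the same order. For the interaction and the averaged effects 100 splits were drawn. Where the real gene count was 0 every split is as large by construction, so the splits say nothing about the gene counts of the interaction (real 0, highest other 135, 100 of 100 as large), of the antibody (0 and 21, 100 of 100) or of the antibody within either genotype. Chance could not be excluded for the gene count of the genotype (1 and 50, 5 of 100), nor for the list counts of the interaction (10 and 20, 64 of 100), the antibody (16 and 20, 28 of 100) or the genotype (13 and 21, 40 of 100). In each of these 3 designs 1 split called more than 10 genes, which may point to a structure of the samples that was neither identified nor tested. For the averaged effects that split had the 2 libraries that stand apart on the same side, and for the interaction on opposite sides. They shared a side in 45 of the splits for the antibody and the interaction and in 38 for the genotype, so their placement does not by itself give such a count. These counts concern how many genes or lists were called, while the separation of Ifngr1 by genotype has its own exact test in the report.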

How the results depend on the processing

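Alternatives without the 2 libraries that stand apart, and list tests other than those with an estimated correlation or fry, were chosen only after the results were seen. Each result was counted once per setting, so a gene or list can appear many times. A gene or list was labelled the same when its sign and call were kept, whatever the change in size. Counts were labelled the same within 1.5 times, and the gene counts with all libraries were 0 or 1. In all, 168 gene counts, 33 list counts, 72 list results, 484 results of named genes and 6 correlations were labelled the same. The others were 13 gene counts, 31 list counts and 3 correlations that moved, and results of lists and of named genes. Of the lists, 37 results lost their call and 3 turned. Of the genes, 5 results lost their call, all of them for Ifngr1, 4 gained one and 6 turned. With relative log expression scaling, limma voom, either filter, the title block, removal of genes near Ifngr1, or 1 library left out, each gene count stayed within 1.5 times. Of the correlations, the antibody effects had r = 0.0883 without the 2 libraries, and the shared-control pair had 0.403 without them and 0.166 at a mean log2 CPM of at least 4. The cause was not tested for any change below, except that fewer samples leave less power.

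DESeq2 called 2 genes for genotype under isotype, 2 under anti-TNF, 4 for genotype on average and 6 for the antibody on average. With only samples titled 40 the counts were 0 for genotype under isotype, 0 under anti-TNF, 0 for both perturbations and 1 for the antibody on average (BC002163). There Ifngr1 was at -1.39 (adjusted p = 0.193), -1.21 (0.264) and -1.18 (0.159) in the first 3, with groups of 2. With only the groups compared, 1 gene (BC002163) was called for the antibody in null/null, 0 for genotype under anti-TNF and 0 for both, with Ifngr1 at -1.33 (0.381) and -1.27 (0.183) and fewer samples to estimate the spread. Without the 2 libraries and with the title block, 2 genes were called for both perturbations (Ifngr1 and Irg1) and 1 for the antibody on average (Irg1).

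The change of Tnf with genotype on average was 0.0687 in limma voom and 0.284 without the 2 libraries, and -0.30 to 0.349 with 1 library left out (highest without wt/null anti-TNF 2). For the antibody on average, leaving out 1 library gave -0.0193 to 0.0296 for Ifngr2, -0.0575 to 0.00772 for Tnfrsf1a and -0.0743 to 0.0149 for Tnfrsf1b, none of them called.

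With all libraries the number of lists called was 0 in each of the 8 comparisons with an estimated correlation and 0 in each with fry for a shared direction. With an estimated correlation and without the 2 libraries it was 1 in all, the IFN-γ-inducible list for genotype on average (0.0433). For changes in either direction fry called 1 list, the TNF and IFN-γ signalling genes that include Ifngr1, in each of the 3 genotype comparisons and for both perturbations. The remaining counts of this paragraph are those of camera at the preset correlation. Without the 2 libraries the number of lists called was 5 for the antibody in wt/null, 5 for the interaction and 10 for the antibody on average. With the block as well it was 7 and 9 for the antibody in wt/null and on average. With 1 library left out it was 4 (without wt/null anti-TNF 2) to 18 for the antibody in wt/null, 5 (without wt/null isotype 2) to 19 (without null/null isotype 2) for genotype under isotype, and 4 (without null/null isotype 1) to 14 (without null/null isotype 2) for the antibody in null/null. It was 8 to 16 (without wt/null anti-TNF 3) for genotype under anti-TNF and 9 (without null/null anti-TNF 1) to 15 for both perturbations. For the interaction it was 2 (without wt/null anti-TNF 2) to 18 (without null/null anti-TNF 1), and for the antibody on average 9 (without wt/null anti-TNF 2) to 18.

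The IFN-γ-inducible list had adjusted p with an estimated correlation and with fry of 0.551 and 0.864 for genotype under isotype, 0.531 and 0.871 under anti-TNF, 0.198 and 0.566 on average, 0.605 and 0.812 for both perturbations, and 0.442 and 0.554 for the antibody in wt/null. In the last it turned lower without the 2 libraries (0.0769), with the block as well (0.0465) and without wt/null anti-TNF 2 (0.142, against 2.91e-12 without wt/null anti-TNF 3). In the genotype comparisons and for both perturbations it stayed called lower under every other alternative.

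A sex term could not be fitted because every sample read as male. No analysis paired by replicate was run, because the labels carry no replicate numbers that link samples. The letter and digit in the titles might link samples across genotypes, but the labels do not say so, and no pairing by title was run. In simulated data 32.8% to 65.7% of genes changed 1.5-fold were recovered, so smaller changes can be missed at 3 libraries per group. The simulation drew each gene independently, without libraries that stand apart in many genes at once, so recovery in the real libraries can be lower. Larger changes can be missed as well, since edgeR did not call Cxcl9 for genotype over all genes.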

Other observations

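Of the tests in this part, that of the 7 further osteoclast-type genes was written before its result was seen, and the others after. The sample titles start with 40 or 46, and the libraries titled 46 lay at -23.6 to -10.7 on the second principal component (14.7% of variance). In 3 of the 4 groups the library titled 46 had the highest mean of genes that macrophages share with osteoclasts, the bone-resorbing cells of the same lineage, while in null/null isotype it had the lowest (4.80 against 5.01 and 5.66 for the 6 genes first seen, in mean log2 CPM). In a fit with the title number as a term none of the 13 genes passed (edgeR adjusted p from 0.158 to 0.987), and Mmp9 was at 2.32 ± 0.92 (log2 difference 46 against 40 ± SE), Ctsk at 1.80 ± 0.81, Dcstamp, which drives cell fusion, at 1.10 ± 0.24, and Acp5 at 1.03 ± 0.24. Nfatc1, the transcription factor of osteoclast formation, was at 0.55 ± 0.13 and Atp6v0d2 at 0.70 ± 0.28, while the proton pump partners Clcn7 and Ostm1 were at -0.03 and -0.01. edgeR called 2 genes for the title number, Adam19 and Rnase4, both lower in 46, with 1276 at unadjusted p < 0.05. Muscle fibre markers were also higher in 46, by 0.45 on average, in 4 of 4 groups (exact permutation p = 0.0123, the smallest that 81 arrangements can give), and by 0.52 without the 2 libraries that stand apart (p = 0.0278, the smallest of 36).

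A hypothesis is that a set of osteoclast-type genes moves together between the title numbers. The 6 genes first seen (Mmp9, Ctsk, Acp5, Ocstamp, Oscar, Calcr) differed by 1.89 on average (exact permutation p = 0.037), which they may owe to having been picked for it and to the 2 libraries that stand apart, both titled 40 and low in them (1.49 without these, exact permutation p = 0.139). The 7 further genes differed by 0.39 (exact permutation p = 0.037; 0.34 and p = 0.0833 without the same libraries) and were highest in the 46 library in 3 of 4 groups, where the hypothesis asked for 4, so it can neither be kept nor set aside. Depth is argued against, with 0 of the 4 libraries outside the range of those titled 40. Whether genotype or antibody takes part is left open, since the first 6 genes were highest in the 46 library in 3 of the 4 groups, short of the 4 that would argue against it.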
